A study of Danio rerio with 2 samples.

How the data were processed

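Olfactory epithelium, the sensory sheet of the nose, was taken from 2 male zebrafish of the AB strain, 1 blank control fish and 1 fish exposed to alarm substance. The epithelium pair of each fish was dissociated with papain and made into 1 droplet library with 10x Genomics chemistry, in which each captured transcript carries a unique molecular identifier (UMI), per the labels' protocols. Groups were taken from the treatment labels. The deposited matrices hold raw UMI counts per gene and barcode with no normalization by the authors. Per the submitters' processing notes, the authors used Cell Ranger 3.1.0, STAR (its version is not given in the sources used here) and build GRCz11, while the matrix headers name software version 3.0.1. The annotation release is not given in the sources used here. The matrices list 32057 genes under 28719 distinct symbols, and 3943 genes share their symbol with another gene, so each gene was kept apart by its Ensembl identifier. The barcodes in the files start at 501 UMIs in the control library and 500 UMIs in the alarm substance library.

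Cells were kept when they had at least 300 genes detected, at most 20% of UMIs from mitochondrially encoded genes and no doublet call by Scrublet, run on each library with an expected doublet rate of 6%. Scrublet called 1 doublet in the control library and 2 in the alarm substance library, far too few to count as a working doublet filter, so leaving out the 6% of cells with the highest Scrublet scores in each library was added as an alternative after the data were seen. Counts of kept cells were scaled to 10000 UMIs per cell and log transformed, 2000 highly variable genes were chosen within each library and combined, and 30 principal components, a graph of 15 neighbours and Leiden clustering at resolution 1 gave 24 clusters of both libraries together, without batch integration. Clusters were named from 27 lists of cell type markers fixed before the data were examined, with at least 3 detected markers for a name. Clusters led by genes that go against any 1 name were called by their leading gene, such as calb2a-high neurons. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and umap-learn 0.5.12, and figures were drawn with matplotlib 3.10.9.

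Each group is 1 fish, so cells are not replicates and no test, p-value or count of changed genes was made. Shares of cells are given with exact (Clopper-Pearson) 95% binomial intervals. For expression, raw UMIs were summed over the kept cells of a class in each library and scaled by the class total to CPM units. The log2 ratio of alarm substance over control had 0.5 UMI added to each sum and an exact conditional 95% interval for the ratio of 2 Poisson counts. All these intervals cover counting error only, not the spread between fish. Those for expression take each UMI as an independent count and leave out the spread between cells. They are therefore too narrow where few cells hold most UMIs, as for receptor genes and lists. The 10 classes with at least 100 kept cells in each library were compared, over genes with at least 50 UMIs in both libraries together. A gene at 0 in 1 library is given as a bound against a floor of 3 counts over the class.

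A total of 29 gene lists were fixed before the data were examined: immediate-early, heat shock and chaperone, ER stress, oxidative stress and NRF2, glucocorticoid response, inflammatory mediators, interferon and antigen presentation, ribosomal proteins, mitochondrially encoded, nuclear oxidative phosphorylation, glycolysis and hypoxia, proteasome, the OR, TAAR, V2R and ORA receptor families, ciliated neuron transduction, microvillous and crypt neuron transduction, synaptic vesicle, neuronal growth, S phase, G2/M, apoptosis and p53, circadian clock, cilium, mucus and barrier, xenobiotic metabolism, purine receptors and haemoglobin. For each list and class the median log2 ratio of its measured members was set among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. A list with fewer than 5 measured members got no percentile. Lists are called higher or lower below only where the median lay outside 2.5 to 97.5% of the random lists. The calculations were tested on simulated data at the depth of the mature ciliated comparison, with 10587 genes. There the intervals held the simulated 2-fold ratio for 96.8% of changed genes and a ratio of 1 for 95.7% of unchanged genes. Of 100 lists of unchanged genes, 7 lay outside the 2.5 to 97.5% range. Genes were drawn independently there, so this rate does not cover lists of genes that vary together between 2 libraries. In the data, 102 of 232 pairs of list and class lay outside that range.

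Genes were named by a rule of size fixed before the data were examined. Genes were ranked by the bound of the 95% interval nearest to 0. In the mature ciliated class the first 10 in each direction were named, in every other class the first 5, and across classes the 5 in each direction beyond 1.5-fold in most classes. Up to 4 members of each list and 5 receptors in each direction were also taken. The genes mtbl, mhc1lba and mhc1uma, the dap1b pair and the sum over 5 MHC genes were chosen after their values were seen. Ribosomal, mitochondrially encoded and haemoglobin genes were left to their lists, and genes whose symbol is a clone or locus identifier were passed over unless among the first 3 (10 higher and 13 lower were passed over in the mature ciliated class). Names of the form of 2 letters, 6 digits and a decimal number were treated the same way. For shares of cells with a receptor UMI, each cell was thinned to 1500 UMIs and shallower cells were left out. The order of neighbouring genes was taken from a RefSeq gene table of assembly GRCz12tu, matched by name, and since this is not the build of the files no coordinates are given.

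Alternatives fixed in advance were no filter on barcodes, a stricter filter (at least 500 genes and at most 10% mitochondrial UMIs), doublet calls kept, Leiden resolutions 0.5 and 2, clustering on genes scaled within each library, scaling by the median of gene ratios, totals without ribosomal, mitochondrial and haemoglobin genes, the mean of each cell's CPM, thinned cells, and list members with at least 20 or 200 UMIs. Leaving out cells with at least 20 haemoglobin UMIs was added after the data were seen. So were the 2 limits of the stricter filter 1 at a time, applied to kept cells without new clustering. In alternatives with new clusters, a cluster took the class of most of its cells kept in the main setting. Where few of its cells had been kept there, it took the class with the closest profile or was called low in gene content.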

Results

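Gene expression was measured in single cells of the zebrafish olfactory epithelium, the sheet of sensory neurons, basal cells and epithelial cells that lines the nose. The series holds 2 libraries, 1 from a control fish given a blank and 1 from a fish exposed to alarm substance, a cue released from injured skin that triggers fear behaviour in fish. The dose and duration of the exposure are not given in the sources used here. The control library held 5989 barcodes with 22355682 UMIs in all and a median of 2850 UMIs and 1063 genes per barcode. The alarm substance library held 7981 barcodes with 29043223 UMIs and a median of 2849 UMIs and 998 genes. After filtering, 3529 control cells (58.9%) and 4996 alarm substance cells (62.6%) were kept, with median depths of 3397 and 3530 UMIs. The mitochondrial share of UMIs was higher in the control library, with a median of 15.2% against 13% over all barcodes and 9.78% against 7.67% over kept cells. Each group is 1 fish, so there are no replicates and every difference below is a difference between 2 libraries, with intervals that cover counting error only.

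Clustering of both libraries together gave 24 clusters, among which 6 classes of neurons made up 64.9% of control cells and 62.1% of alarm substance cells. Mature ciliated neuron-like cells expressed ompa, ompb, gnal, cnga4 and adcy3b, genes of the cyclic AMP pathway of odour transduction and its mature neurons. Microvillous neuron-like cells expressed trpc2b, s100z and gnao1b, and immature neuron-like cells expressed gap43, stmn2b, dpysl3 and elavl4, genes of growing neurons. Neurons led by calb2a and neurons led by gnao1a and sox11a were kept as separate classes, as were the few neurons led by gucy1b2. Progenitor-like cells expressed neurod1, neurod4 and dla, genes of neurogenesis. The other compared classes were basal-like cells (tp63, krt15, col17a1b), epithelial cells led by stm, multiciliated-like cells (foxj1a, rsph4a, tekt4), macrophage-like cells led by grn2 and T or NK-like cells (il2rb, zap70, il7r). The grn2-high cells had 9 of 20 macrophage markers detected, among them mpeg1.1, cd74a and spi1a, but not csf1ra, marco or c1qa. Neutrophil-like cells had 17 of these 20 and a small class led by ccl35.1 had 13, so the name of the grn2-high class is uncertain. No cluster was named from the lists for crypt neurons, sustentacular cells, goblet cells, glia, endothelium, fibroblasts, mural cells, thrombocytes, erythrocytes, pigment cells, muscle or olfactory bulb neurons.

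The first comparison asks whether the cell types of the epithelium stood in other proportions in the fish exposed to alarm substance. Mature ciliated neuron-like cells were a smaller share of the cells, 27.0% (95% interval 25.8 to 28.3) in the alarm substance library against 35.5% (33.9 to 37.1) in the control library. Immature neuron-like cells were a larger share, 9.21% (8.42 to 10.0) against 4.68% (4.00 to 5.43), and so were the gnao1a-high neurons, 8.91% (8.13 to 9.73) against 4.76% (4.08 to 5.52). Progenitor-like cells made up 2.42% against 0.992% of cells. T or NK-like cells made up 6.43% (5.76 to 7.14) against 3.71% (3.11 to 4.39), and 45 B-like cells were found against 4. Superficial epithelial-like cells made up 1.28% (0.988 to 1.63) against 0.368% (0.196 to 0.629), or 64 cells against 13. Ionocyte-like cells made up 2.88% against 1.87%. This difference of 1.01 percentage points was 0.176 (−0.693 to 1.03) with no filter.

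Microvillous neuron-like cells were 10.4% against 12.8%, basal-like cells 5.91% against 7.31% and multiciliated-like cells 2.82% against 3.91%. These differences of −2.44, −1.41 and −1.09 percentage points became −0.859 (−1.79 to 0.062), −0.601 (−1.46 to 0.24) and −8.46 with no filter, and −4.94, −3.71 and −1.27 with at least 500 genes and at most 10% mitochondrial UMIs. That of microvillous neuron-like cells was −1.13 (−2.51 to 0.23) with genes scaled within each library. The shares of stm-high epithelial cells, calb2a-high neurons and grn2-high macrophage-like cells differed by −0.264, −0.238 and 0.127 percentage points, each with an interval that includes 0. With the 2 stricter limits those of stm-high cells and calb2a-high neurons differed by −1.82 (−3.21 to −0.51) and −2.96 (−4.66 to −1.33), and stm-high cells stood at −2.14 (−3.48 to −0.83) at clustering resolution 0.5. Among neurons and progenitor-like cells alone, mature ciliated neuron-like cells were 41.9% against 53.8% and immature neuron-like cells 14.3% against 7.09%. A mixed cluster that carried neuronal and epithelial genes at high UMI counts held 79 control cells and 20 alarm substance cells, 71 and 8 without the highest Scrublet scores, and 9 and 8 with at most 10% mitochondrial UMIs. The filter bore on these shares: with no filter, left-out barcodes took the class of the kept cells they clustered with, wherever enough were kept. Of 780 control and 364 alarm substance barcodes named multiciliated in this way, 645 and 150 had been left out by the filter. This class had a median mitochondrial share of 39.1% and 11.06%, and its left-out barcodes need not be multiciliated cells. With at most 10% mitochondrial UMIs the difference in mature ciliated neuron-like cells turned from −8.44 to 3.64 percentage points, or to 2.59 with at least 500 genes as well and cells clustered anew. It was −4.19 with no filter. The difference of 4.53 points in immature neuron-like cells was 3.88 and 4.67 under these limits, but 1.74 with no filter, 1.99 at clustering resolution 0.5, 2.25 with genes scaled within each library and 2.87 with doublet calls kept. That of gnao1a-high neurons, 4.15, lay between 2.95 with at most 10% mitochondrial UMIs and 6.28 at resolution 0.5, and that of T or NK-like cells went from 2.71 to 1.73 with at most 10% mitochondrial UMIs.

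**Figure D1:**
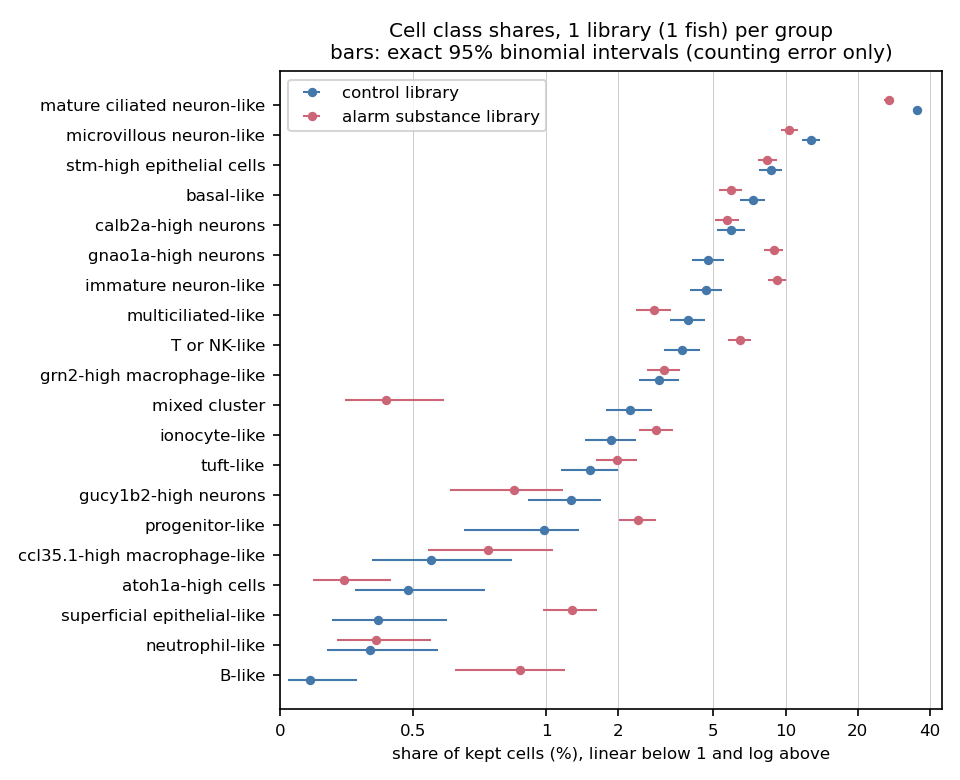
Share of kept cells in each class (%, horizontal axis) in the control and the alarm substance library, 1 fish each, with exact 95% binomial intervals. Mature ciliated neuron-like cells stand at 35.5% and 27.0%, and immature neuron-like cells at 4.68% and 9.21%.

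The next comparison asks which genes differed in level across many cell classes at once, with the alarm substance value given first and set against the control value. The metallothionein gene mt2 (ENSDARG00000041623), which encodes a small metal-binding protein, was lower in the alarm substance library in 9 of the 10 classes. In mature ciliated neuron-like cells it stood at 596 CPM against 9727 CPM, a 16.3-fold lower level (log2 ratio −4.03, 95% interval −4.09 to −3.97). It was 11.7-fold lower in microvillous neuron-like cells, 12.8-fold lower in stm-high epithelial cells and 14.7-fold lower in T or NK-like cells. The grn2-high macrophage-like cells stood apart, with a log2 ratio of −0.18 (−0.47 to 0.11). Over all kept cells the related gene mtbl (ENSDARG00000102051) had a log2 ratio of 0.027 (−0.055 to 0.11).

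Genes of antigen processing in the major histocompatibility complex (MHC) had UMIs almost only in the alarm substance library. Over all kept cells psmb8a (ENSDARG00000001303), psmb12 (ENSDARG00000031885) and psmb13a (ENSDARG00000001656), which encode β-type proteasome subunits, had 574, 676 and 434 UMIs against 0 in the control library, at least 141-fold, 166-fold and 107-fold higher. The peptide transporter gene tap2a (ENSDARG00000036787) had 441 UMIs against 2 (log2 ratio 7.02, 5.48 to 10.39), and psmb9a (ENSDARG00000000656) had 668 against 41. The MHC class I genes went both ways: mhc1lba had 94 UMIs against 0, while mhc1uma had 0 against 41, at least 18.6-fold lower. The 5 proteasome and transporter genes together were higher in each of the 10 classes, from 56.3 against 4.06 CPM in basal-like cells to 483 against 3.28 CPM in T or NK-like cells.

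Of the genes higher by over 1.5-fold in most classes, hspe1 (ENSDARG00000056167), the mitochondrial co-chaperonin, was so in 10 of 10 classes with a median log2 ratio of 1.47 (range 1.16 to 1.94). The complement regulator gene rca2.1 was higher in 9 classes (median 1.30), and mlf1 (1.68), the endoplasmic reticulum selenoprotein gene selenok (1.33) and the MHC class I gene mhc1zba (0.94) in 8 each. The uncharacterised gene zgc:194659 (ENSDARG00000079347) was higher in all 9 classes in which it was measured, with 6102 UMIs against 3. Among genes lower in most classes were the ubiquitin ligase gene rnf213a (8 classes, median −1.11), rasgrf2b (8 of 9, −1.02), the cytochrome c oxidase gene cox7c (8, −0.90) and the LIM domain gene crip1 (7 of 8, −1.81), with the uncharacterised CU104709.1 lower in 10 of 10 (−1.38). The symbol dap1b covers a pair of genes that went opposite ways over all kept cells, with 1844 UMIs against 754 for ENSDARG00000086842 and 2 against 163 for ENSDARG00000109678. In CPM the median log2 ratio of all genes was −0.13 in microvillous neuron-like cells and −0.11 in basal-like cells, against which the values of those classes stand.

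**Figure D2:**
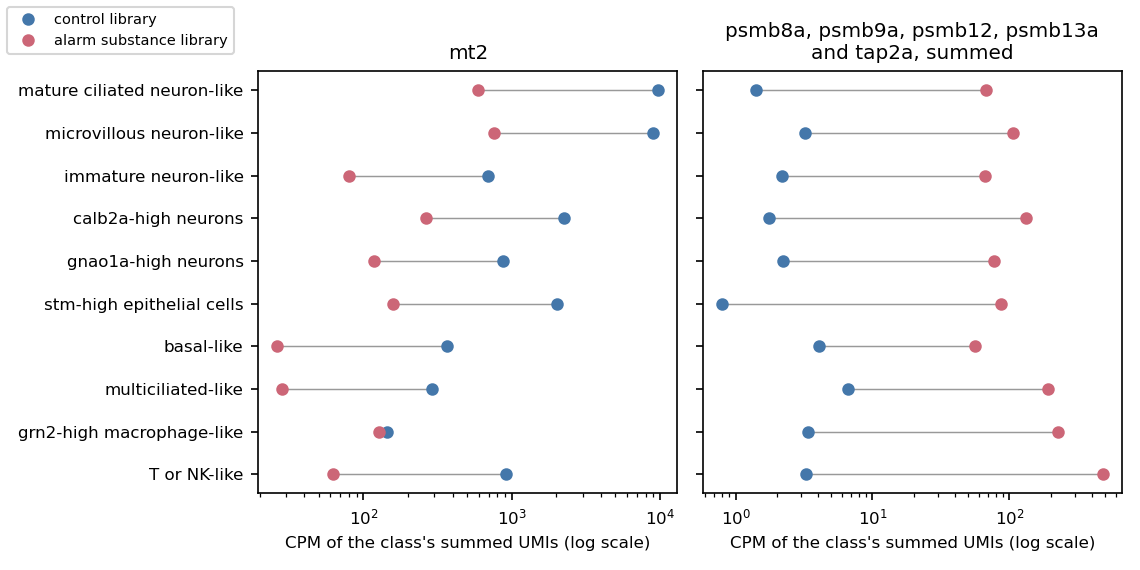
Level of mt2 and summed level of the 5 MHC proteasome and transporter genes (CPM, log axes) in each of the 10 classes in the control and the alarm substance library, 1 fish each. mt2 was 9727 and 596 CPM in mature ciliated neuron-like cells and 144 and 127 CPM in grn2-high macrophage-like cells.

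Immediate-early genes, which neurons and other cells switch on within minutes of stimulation, address whether cells of the exposed fish carried a trace of recent activation. The list was higher in most neuronal classes and lower in several others. In immature neuron-like cells 26 of 27 measured members were higher, with a median log2 ratio of 0.71 (0.60 to 0.85), or 0.45 with at least 500 genes and at most 10% mitochondrial UMIs, led by the kinase gene sik1 (1.84), the nuclear receptor gene nr4a1 (1.71, 1.33 to 2.15) and the AP-1 genes jun (1.04) and fosl2 (1.04). In gnao1a-high neurons 24 of 28 were higher (median 0.39), with sik1 at 1.11 and nr4a1 at 0.97. In microvillous neuron-like cells 20 of 27 were higher (median 0.39, or 0.52 under scaling by the median of gene ratios and 0.19 under those 2 limits), with egr4 at 1.18 and jun at 0.99. In mature ciliated neuron-like cells 26 of 37 were higher (median 0.19, 0.15 to 0.32), with csrnp1a at 1.73, egr4 at 1.53 and fosl2 at 0.91, but with at most 10% mitochondrial UMIs this median turned to −0.17, or to −0.082 with at least 500 genes as well.

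Of the 10 compared classes, multiciliated-like cells had the lowest median for this list, −0.68 (−0.84 to −0.58), with 33 of 39 members lower. The zinc finger gene egr2a was 10.4-fold lower there (110 UMIs against 936), and btg2 (−2.38), egr2b (−2.12) and fosab (−1.70) were lower as well. In basal-like cells 33 of 44 members were lower (median −0.60, or −0.49 under scaling by the median of gene ratios), with egr2a at −1.90, klf4 at −1.62 and fosb at −1.10, against rgs2 at 3.58. In T or NK-like cells 24 of 30 were lower (median −0.34), with nr4a3 at −1.48 and egr3 at −1.32. The medians of calb2a-high neurons (0.11), grn2-high macrophage-like cells (0.050) and stm-high epithelial cells (−0.13) lay within those of random lists. In calb2a-high neurons egr4 was higher (2.38) while npas4a (−1.29) and fosab (−0.43) were lower.

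**Figure D3:**
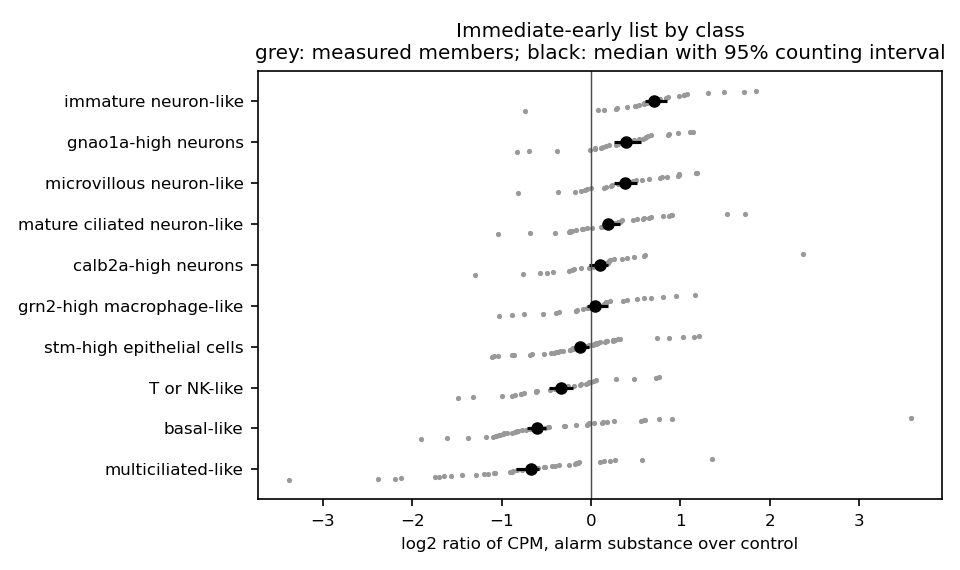
Log2 ratio (alarm substance over control) of the members of the immediate-early list in each class, with points for genes and the class median marked, 1 fish per group. The medians run from 0.71 in immature neuron-like cells to −0.68 in multiciliated-like cells.

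Stress genes ask whether protein folding and damage responses differed between the fish. Heat shock and chaperone genes were higher in microvillous neuron-like cells (31 of 37, median 0.49), gnao1a-high neurons (0.42), immature neuron-like cells (0.40), multiciliated-like cells (0.39), mature ciliated neuron-like cells (29 of 40, 0.27), grn2-high macrophage-like cells (0.22) and stm-high epithelial cells (0.095). Besides hspe1, the chaperone genes hsph1 (1.93) and hspa4a (1.35) led in microvillous neuron-like cells, and hsph1 was at 1.36 in multiciliated-like cells. In grn2-high macrophage-like cells the inducible hsp70l (−1.61) and hsp70.1 (−1.49) were lower, and the list's summed counts had a log2 ratio of −0.010. The medians were 0.027, 0.017 and −0.0063 in calb2a-high neurons, basal-like cells and T or NK-like cells. Genes of ER stress were higher in 7 classes, from gnao1a-high neurons (20 of 26, 0.51) and multiciliated-like cells (25 of 31, 0.47) to mature ciliated neuron-like cells (22 of 31, 0.25), where the median turned to −0.018 with at least 500 genes and at most 10% mitochondrial UMIs. The disulfide isomerase gene pdia6 was higher by 1.11 to 1.75 on the log2 scale in stm-high epithelial cells, immature neuron-like cells, gnao1a-high neurons, multiciliated-like cells and grn2-high macrophage-like cells.

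Apoptosis and p53 genes were higher in microvillous neuron-like cells (16 of 21, 0.45), with the cell cycle inhibitor gene cdkn1a at 1.15, in grn2-high macrophage-like cells (0.36), immature neuron-like cells (0.34) and mature ciliated neuron-like cells (0.18). The p53 regulator gene mdm2 was at 2.34 in multiciliated-like cells. In the oxidative stress and NRF2 list, 20 of 30 members were lower in mature ciliated neuron-like cells (median −0.19), with mt2 and the microsomal transferase gene mgst3b (−1.80) lower and the glutathione peroxidase gene gpx1b higher (2.12) while gpx1a was lower (−1.41). The glucocorticoid response list, which holds genes of the stress hormone receptor, had a median of −0.12 in mature ciliated neuron-like cells, within random lists, although its receptor-bound chaperone gene fkbp5 was at 1.04 (0.90 to 1.19). The list was higher in basal-like cells (16 of 24, 0.26), in stm-high epithelial cells (17 of 27, 0.20), where thinned cells turned it to −0.073, and in immature neuron-like cells (7 of 12, 0.21), where the mean over cells turned it to just below 0, with fkbp5 at 2.35, pdk2b at 4.00 and lpin1 at 2.04 in stm-high epithelial cells. Its summed counts were lower in all 10 classes, with mt2 among its members.

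Metabolic and housekeeping lists were compared in the same way. Mitochondrially encoded genes were lower in all 10 classes, with medians from −0.78 in calb2a-high neurons to −0.32 in multiciliated-like cells, and 13 of 13 were lower in mature ciliated neuron-like cells (−0.63), led by mt-nd1 (−1.12) and mt-nd4 (−1.05). These genes also make up the mitochondrial share that the cell filter used, with medians of 7.67% against 9.78% in kept cells. This list therefore cannot be told apart from a difference in cell quality between the libraries. Nuclear genes of oxidative phosphorylation were lower in 8 classes, from −0.50 in basal-like cells and −0.34 in immature neuron-like cells to −0.066 in multiciliated-like cells, which turned to 0.022 in thinned cells. In mature ciliated neuron-like cells this median was −0.12, but cox4i1l (1.89) and ndufv3 (1.63) were higher and the summed counts had a log2 ratio of 0.0060. Proteasome genes of the standard particle were lower in basal-like cells (−0.58), microvillous neuron-like cells (35 of 38 lower, −0.41), immature neuron-like cells (−0.37), stm-high epithelial cells (−0.34) and mature ciliated neuron-like cells (34 of 39 lower, −0.31), with the regulatory subunit gene psmd1 at −0.95 in the last. Ribosomal protein genes were higher in 7 classes, among them calb2a-high neurons (0.34), mature ciliated neuron-like cells (72 of 83, 0.28) and T or NK-like cells (0.083, which turned to −0.019 with at least 500 genes and at most 10% mitochondrial UMIs), while rpl29 was lower in each of the 10 classes, −0.77 in mature ciliated neuron-like cells. Glycolysis and hypoxia genes lay within random lists in all 10 classes (−0.25 to 0.12).

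Circadian clock genes were higher in 9 of 10 classes, from 0.29 in mature ciliated neuron-like cells (22 of 29) to 0.52 in grn2-high macrophage-like cells. The PAR leucine zipper gene tefb (1.42) and the repressor gene nfil3-6 (1.18) led in mature ciliated neuron-like cells, and the nuclear receptor gene nr1d1 (2.05) led in stm-high epithelial cells. In T or NK-like cells the median was 0.22, within random lists. The interferon and antigen presentation list, which holds the MHC genes above, was higher in stm-high epithelial cells (0.57), mature ciliated neuron-like cells (22 of 27, 0.49), multiciliated-like cells (0.49), basal-like cells (0.34) and calb2a-high neurons (0.31), with b2m at 1.06 in the last. Its median was 0.25 in T or NK-like cells, 0.039 in microvillous neuron-like cells, −0.087 in immature neuron-like cells, −0.12 in gnao1a-high neurons and −0.18 in grn2-high macrophage-like cells. The ubiquitin-like gene isg15 was at 1.56 in microvillous neuron-like cells.

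**Figure D4:**
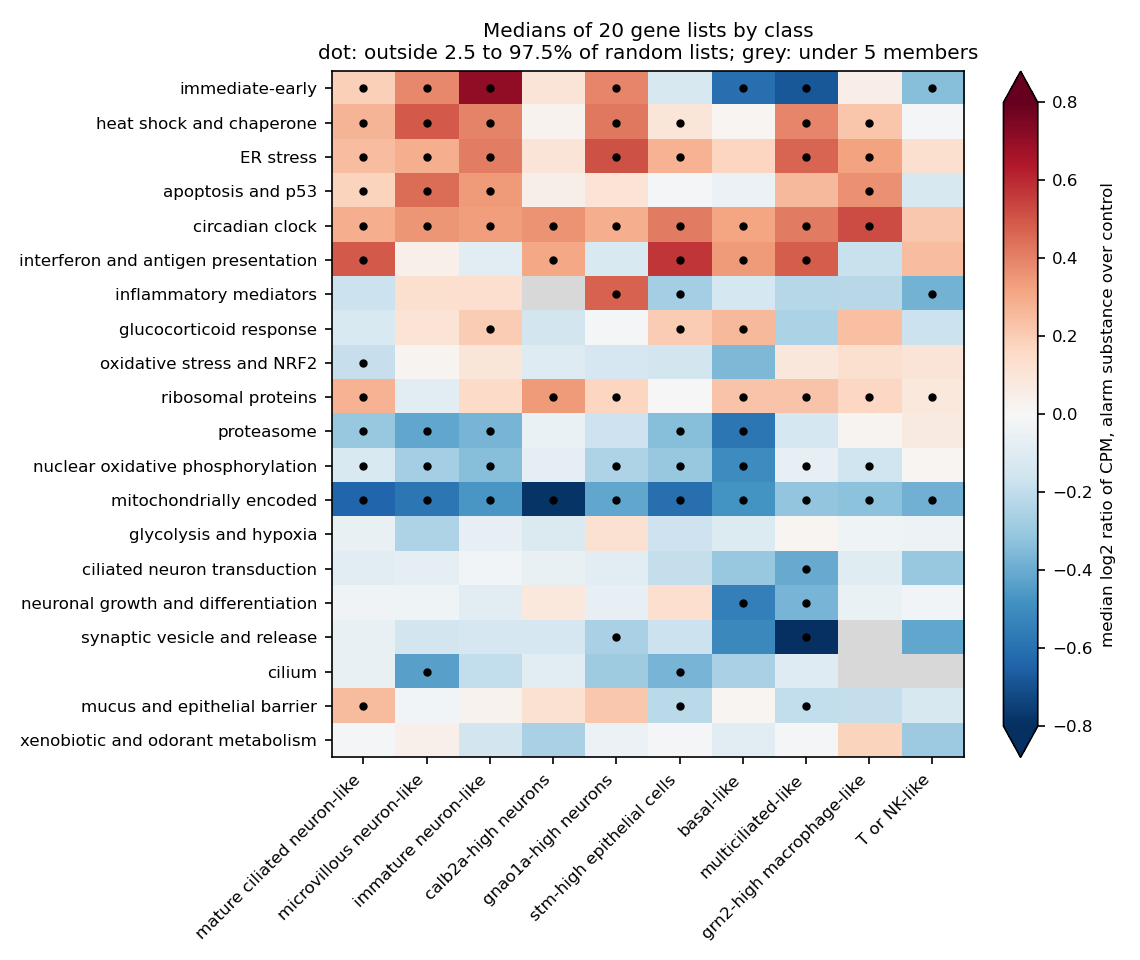
Median log2 ratio (alarm substance over control, colour scale) of each gene list in each of the 10 classes, 1 fish per group. Mitochondrially encoded genes are lower in all 10 classes (−0.78 to −0.32), and the immediate-early list runs from 0.71 to −0.68.

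Mature ciliated neuron-like cells, the main odour-sensing class with 1252 control and 1351 alarm substance cells, were compared gene by gene. Besides zgc:194659, the genes higher in the alarm substance library included the lectin gene clec19a (1075 UMIs against 3, log2 ratio 8.09, 6.76 to 10.60), ribc1, a gene of ciliary microtubules (341 against 2), luzp2 (359 against 3), tap2a, psmb8a and psmb12. Those lower included crip1, 44.5-fold lower (58 UMIs against 2315), si:dkey-56f14.4 (0 against 464, at least 174-fold lower), the sialyltransferase gene st6galnac1.2 (1 against 122), camkvl (7.09-fold lower) and ccdc33 (9.82-fold lower). The gene si:ch211-5k11.8 had 4 UMIs against 3139, but 98.0% of its UMIs lay in 3 cells. Odorant receptor genes also reached this size, or122-1, or109-7, or113-1 and taar19d among the higher and or126-3, or102-1, or137-9, or125-1 and or109-11 among the lower, each with at least 67.4% of its UMIs in 3 cells. Mature ciliated cells of the libraries fell in different proportions into 3 clusters, with 583, 464 and 205 control cells against 520, 373 and 458 alarm substance cells, and mt2 was lower in each of them (−4.06, −4.11 and −3.32).

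Genes of ciliated neuron transduction had a median of −0.089 in mature ciliated neuron-like cells, within random lists, with the adenylyl cyclase gene adcy3b at −0.66 and ompb at 0.50. The gene adcy3b was a leading gene of the cluster with 373 alarm substance against 464 control cells, and ompb of that with 458 against 205. Their values may thus follow the mix of clusters, which was not tested for these 2 genes. Synaptic vesicle genes (−0.058), neuronal growth genes (−0.029), cilium genes (−0.061), inflammatory mediators (−0.17), xenobiotic metabolism genes (−0.016) and purine receptors and metabolism (−0.20) also lay within random lists in mature ciliated neuron-like cells. Among these members the transcription factor gene ebf2 was at −2.65, the synaptotagmin gene syt5a at 1.05 and the adenosine kinase gene adka at −2.08. S phase genes were higher (9 of 13, 0.71), with ccnd1 at 1.00 and pcna at 0.46, and 4 members of the G2/M list were measured, with hmgb2a at 0.11. Mucus and barrier genes were higher (13 of 20, 0.25), with krt91 at 1.44, and this median turned to −0.01 with at least 500 genes and at most 10% mitochondrial UMIs. Haemoglobin genes were lower (5 of 5, median −9.04, or −7.43 with absent genes at the floor), and 3 kept control cells held 3459 of the 3640 haemoglobin UMIs of that library.

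In the other neuronal classes zgc:194659 and mt2 again stood among the genes that differed most. Microvillous neuron-like cells had higher cabp1b, a calcium-binding protein gene (172 UMIs against 13, 10.9-fold), and the microtubule gene map1ab (11.07-fold), and lower crip1 (3 UMIs against 133, 44.8-fold) and CR933791.1 (0 against 64, at least 25.1-fold lower). Their transduction genes had a median of −0.077, within random lists, while cilium genes were lower (26 of 29, −0.43). Calb2a-high neurons had higher slc24a2, a sodium, potassium and calcium exchanger gene (63 UMIs against 1), and ribc1 (61 against 0, at least 14.03-fold higher), and gnao1a-high neurons had higher kif26ba (57 against 0, at least 6.96-fold) and lower rsph9, a gene of the ciliary radial spoke (5.1-fold). Synaptic vesicle genes were lower in gnao1a-high neurons (−0.26), with the vesicular glutamate transporter gene slc17a6b at −0.92, and inflammatory mediators there stood at 0.47 over 5 members. In immature neuron-like cells the uncharacterised CU929418.1 was higher (153 UMIs in 119 cells against 0, at least 16.2-fold) and cyp3c4 was 4.75-fold lower, while receptor genes such as v2rc1 and v2ra18 (85 and 83 UMIs against 0) had most of their UMIs in 3 cells.

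Among epithelial classes, basal-like cells had higher sat1a.1, which encodes a polyamine acetyltransferase (365 UMIs against 25, 9.48-fold), chst11 (15.02-fold) and the chemokine genes ccl19b (2.95) and cxcl14 (2.33), and lower her15.1, a Notch pathway target (2 UMIs against 75), and the proliferation marker mki67 (7 against 69). Few cells carried these 2 genes, with 68.8% of her15.1 and 76.3% of mki67 UMIs in 3 cells. All 3 measured G2/M genes and all 5 measured S phase genes had values below 0 in them. In stm-high epithelial cells inflammatory mediators were lower (15 of 23, −0.27), led by the cytokine gene il11b (−2.53), as were mucus and barrier genes (19 of 28, −0.21) and cilium genes (34 of 40, −0.37), while S phase genes were higher (8 of 8, 0.46). Multiciliated-like cells had higher ribc1 (410 UMIs against 0, at least 111-fold) and pvalb6 (14.8-fold), and lower cfap157, a gene of cilia and flagella (27.3-fold), mucus and barrier genes (−0.20) and G2/M genes (−0.36). Neuronal genes were lower in multiciliated-like cells, where the microvillous and crypt neuron transduction list stood at −1.48, synaptic vesicle genes at −1.002, ciliated neuron transduction genes at −0.40 and neuronal growth genes at −0.37, with s100z 7.04-fold lower but 70.0% of its UMIs in 3 cells. The microvillous and crypt neuron transduction list (−0.93) and the neuronal growth list (−0.55) were also lower in basal-like cells, but the latter turned to 0.0026 without the highest Scrublet scores. There trpc2b was 7.08-fold lower, with 71.7% of its UMIs in 3 cells. Neuronal UMIs in these epithelial classes may stem from doublets or free RNA as well as from the cells themselves, which was not settled here. The values are therefore not read as expression of epithelial cells.

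Among classes with immune markers, grn2-high macrophage-like cells had higher cyp1a, the classical target of the aryl hydrocarbon receptor. It had 1076 UMIs in 66 cells against 9 UMIs in 1 cell (log2 ratio 6.19, 5.34 to 7.40). Also higher in these cells was ahrra (2.51), which encodes that receptor's repressor. The Ly6 family genes ly6m5 and ly6m2 had 325 and 137 UMIs there against 0 (at least 69.9-fold and 29.5-fold higher). The chemokine receptor gene xcr1a.1 was 7.43-fold lower and the cytokine gene il1b was at −2.28. Purine receptors and metabolism (6 of 6 lower, −0.89), S phase genes (−0.61) and G2/M genes (−0.44) were lower in these cells, and the xenobiotic metabolism list as a whole (0.18) lay within random lists. The epithelial gene stm, with 19 UMIs against 93, and muc5.1 were lower in them too, with 69.6% and 83.3% of their UMIs in 3 cells. In T or NK-like cells the chemokine genes ccl36.1 (1 UMI against 61) and ccl38.6 (5.84-fold lower) were lower and cxcl19 was higher (2.67), with inflammatory mediators lower as a list (12 of 17, −0.38), and fcer1g (4.62-fold) and rnf19b (4.29-fold) were lower as well.

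The last comparison asks whether the neurons of the exposed fish drew on other receptor genes. Of 247 receptor genes in the OR, TAAR, V2R and ORA lists, 222 were detected in 2028 thinned control neurons and 235 in 2614 thinned alarm substance neurons, or a mean of 230 (224 to 235) when 2028 cells were drawn. A receptor UMI was found in 77.0% (75.4 to 78.7) of alarm substance neurons against 79.2% (77.4 to 81.0) of control neurons, at 1500 UMIs per cell. The background in T or NK-like cells at the same depth was 17.5% and 22.1%. Of cells with a leading receptor, OR genes led in 53.5% (51.3 to 55.6) against 59.1% (56.7 to 61.5), TAAR genes in 21.96% (20.2 to 23.8) against 18.4% (16.5 to 20.4), V2R genes in 24.1% against 21.6% and ORA genes in 0.477% against 0.919%. These family shares pool neuron classes whose proportions differed between the libraries, and they were not computed by class. In both libraries 190 receptor genes led in some cell, of 203 in the control and 223 in the alarm substance library.

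Single receptor genes over all neurons differed in both directions. Those furthest from 0 by the rule for named genes were taar19g (349 UMIs against 1), or122-1 (144 against 1), taar19o (90 against 1), or109-7 (140 against 3) and or113-1 (58 against 0) among the higher, and or137-9 (1 against 96), or125-1 (0 against 61), olfcg8 (10 against 220), or109-11 (3 against 79) and taar20n (4 against 79) among the lower. Each rested on few cells, as olfcg8 led in 14 control and 2 alarm substance cells. By class, the OR list stood at 0.11 in mature ciliated neuron-like cells (37 of 70 higher), which turned to −0.079 with at least 500 genes and at most 10% mitochondrial UMIs. It stood at −0.77 in stm-high epithelial cells, where receptor UMIs may stem from doublets or free RNA. In calb2a-high neurons the OR list stood at −0.72 over 8 members (2 higher) but at 1.46 with members of at least 20 UMIs, and its summed counts were at −0.037 (−0.17 to 0.10). The TAAR list of 93 genes stood at 1.81 in gnao1a-high neurons (11 of 13 measured members higher). It stood at 3.06 in immature neuron-like cells (6 of 6, or 2.68 with absent genes at the floor). Members counted as measured by their UMIs over both libraries together. The alarm substance library held more UMIs in these classes, 1225497 against 449147 and 1449705 against 461089. Receptors of few alarm substance cells thus entered more readily than those of few control cells. This choice favours higher members, so these counts and medians do not show a higher list. The summed counts of the whole list were at 0.23 (0.082 to 0.38) and 0.52 (0.29 to 0.75). The TAAR medians were −0.055 in mature ciliated neuron-like cells and 0.081 in calb2a-high neurons. The V2R list stood at −0.29 in microvillous neuron-like cells (17 of 35 higher), within random lists, and ora1, the measured ORA gene, at −1.37 there, in 2 cells against 7.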

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

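All tests of explanations below except that of the exposure were chosen only after the results they address were seen. Differences between cell classes were singled out because a list was higher in 1 class and lower in another, and these differences were not tested against variation between fish.

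The immediate-early list differed by 1.38 on the log2 scale (1.22 to 1.61) between immature neuron-like cells (0.71) and multiciliated-like cells (−0.68). The list was singled out because classes lay on both sides of 0, and its highest and lowest classes were then compared. The comparison could therefore not have favoured 1 shift common to all classes of a library, such as a scaling difference, and does not test it. The interval does not cover the choice of these 2 classes. Mitochondrial content of the kept barcodes is argued against only weakly as the whole cause outside the mature ciliated class. There 6 of 6 classes kept their sign beyond 0.1 with at most 10% mitochondrial UMIs as the only limit altered. The test is weak because this limit kept most cells of these classes. Of immature neuron-like cells it kept 99 of 165 in the control and 308 of 460 in the alarm substance library. Of mature ciliated neuron-like cells, whose median changed sign, it kept 384 of 1252 and 816 of 1351. That content may still account for a part, since the stricter filter gave smaller medians in immature and microvillous neuron-like cells. In basal-like cells the stricter filter gave a more negative median. In mature ciliated neuron-like cells the median went to −0.17 and may follow that content. Exposure to the alarm substance stays open and cannot be told apart from other differences between the fish, with 1 fish per group. A different delay between dissection and lysis in the libraries, which dissociated neurons and epithelial cells may answer each in their own way, also stays open and was not tested.

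The MHC genes psmb8a, psmb12, psmb13a, psmb9a and tap2a had UMIs almost only in the alarm substance library. An interferon response is argued against, since the 38 other members of that list had a median log2 ratio of 0.21 (0.16 to 0.39) over all kept cells. All 10 classes carried the difference, which argues against a cell type missing from the control library as long as RNA stayed in its cells. Free RNA spread from such a cell type would also reach all classes and was not tested for these genes. A candidate explanation is that the fish carry different MHC haplotypes, which in zebrafish differ in their sets of psmb and tap2 genes. Of 21 other genes with a ratio interval beyond 8-fold and at most 3 UMIs in 1 library, 2 had another such gene among their nearest measured neighbours, which does not pass the upper 95% bound of 2 in random draws, while of the 35 genes chosen by that ratio alone 4 did, above the same bound. Different gene content or alleles therefore cannot be told apart from shared regulation, reads shared between relatives such as ly6m2 and ly6m5, or the exposure. The neighbours ly6m2 and ly6m5 were both higher. The 2 neighbours among the 21 genes went opposite ways, si:dkey-30g5.1 with 65 UMIs against 0 and zgc:172090 with 3 against 62. A regulation that raises or lowers both genes would not give this, but 1 pair does not decide the cause.

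The gene mt2 was lower in the alarm substance library in 9 of 10 classes. A variant of the fish in mt2 itself is argued against, since the log2 ratio in grn2-high macrophage-like cells was −0.18 (−0.47 to 0.11). Mitochondrial content is argued against as the whole cause by a ratio of −3.67 (−3.75 to −3.60) in mature ciliated neuron-like cells with at most 10% mitochondrial UMIs as the only limit altered. Free RNA spread evenly over cells from 1 source class of the control library is argued against in microvillous neuron-like and stm-high epithelial cells. They held at least 10.4 times (8.88 to 12.1) the UMIs per cell of the lowest class there. Uneven carry-over was not tested, and stm-high cells also had neuronal markers such as ompa and trpc2b. Even carry-over stays open in the 7 classes of lower level, which differed 3.86-fold at most. A difference in metal exposure or handling of the fish, a regulatory variant and the alarm substance itself stay open and were not tested, with 1 fish per group.

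S phase genes differed by 1.32 on the log2 scale between mature ciliated neuron-like cells (0.71) and grn2-high macrophage-like cells (−0.61). Mucus and barrier genes differed by 0.467 between mature ciliated neuron-like cells (0.25) and stm-high epithelial cells (−0.21). Barcodes left out by the filter were used only in the alternative with no filter. Those of several classes made up a larger share of all barcodes in the alarm substance library. These shares were 1.63% against 1.02% for T or NK-like cells and 2.03% against 1.27% for gnao1a-high neurons. They were 3.15% against 1.97% for superficial epithelial-like cells and 6.65% against 4.41% for barcodes of low gene content. The part of each class left out was not larger there. It was 130 of 454 barcodes against 61 of 195 for T or NK-like cells. It was 162 of 797 against 76 of 320 for gnao1a-high neurons and 251 of 309 against 118 of 134 for superficial epithelial-like cells. Barcodes named multiciliated from the kept cells they clustered with went the other way as a share of all barcodes, with 1.88% against 10.8%.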

How the results depend on the processing

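Leaving out the highest Scrublet scores or the haemoglobin-rich cells, and altering 1 limit of the filter at a time with classes as they were, was chosen after seeing the data, and the other alternatives before. A value was called reversed where its sign turned and the main interval excluded 0, or, for list medians, where the list lay outside random lists. Other turns of sign were not counted, as in calb2a-high neurons, with a share difference of −0.238 but 0.542 with no filter. Of 197 values of class shares 158 lay within the interval of the main setting, 34 moved outside it and 5 reversed. For list medians these counts were 2619, 330 and 12 of 2961 values, for list sums 39, 38 and 0 of 77, for named genes 1453, 105 and 9 of 1567, and both values of the receptor share stayed. Of 232 pairs of list and class with 5 or more measured members, 102 lay outside random lists. Of these 102, 91 kept their sign under every setting run, and none reversed under either alternative scaling. Where a value moved or reversed, the cause was not tested beyond these settings. Single receptor genes rest on few cells, which limits their values.

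Cells kept were 5988 and 7979 with no filter, 1789 and 3162 with the strict filter (at least 500 genes and at most 10% mitochondrial UMIs, clustered anew), 1835 and 3321 with the mitochondrial limit alone and 3365 and 4619 with the gene limit alone. With no filter the difference in share (percentage points) was −4.19 for mature ciliated cells, 1.74 for immature cells and −8.46 for barcodes named multiciliated. It was 1.79 for all neurons, which reversed. With the strict filter it reversed to 2.59 for mature ciliated cells and 3.04 for all neurons. With the mitochondrial limit alone it reversed to 3.64 for mature ciliated cells and 2.68 for all neurons and was 1.73 for T or NK-like cells. With genes scaled within libraries it was −6.35 for mature ciliated and 2.25 for immature cells, which stood at 2.87 with doublet calls kept and 1.99 at resolution 0.5.

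The immediate-early median with the strict filter was −0.082 in mature ciliated (reversed), 0.19 in microvillous, 0.45 in immature and −0.73 in basal-like cells. With the mitochondrial limit alone it was −0.17 in mature ciliated (reversed) and −0.77 in basal-like cells. Under scaling by the median of gene ratios it was 0.52 in microvillous and −0.49 in basal-like cells, in thinned cells 0.14 in mature ciliated and −0.93 in multiciliated cells, and with members of at least 200 UMIs −0.75 in basal-like cells. Other lists reversed with the strict filter in mature ciliated cells (ER stress −0.018, OR −0.079) and in T or NK-like cells (ribosomal −0.019). So did the mucus and epithelial barrier list, median log2 ratio in mature ciliated neuron-like cells −0.00962. In thinned cells glucocorticoid (−0.073) and TAAR (0.25) reversed in stm-high cells and nuclear oxidative phosphorylation (0.022) in multiciliated cells. Also reversed were the glucocorticoid response list, median log2 ratio in immature neuron-like cells −0.00277 as a mean over cells, OR in calb2a-high neurons with at least 20 UMIs (1.46), and neuronal growth in basal-like cells without the highest Scrublet scores (0.0026).

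Of named genes, the strict filter reversed olfch1 in microvillous (−0.63), si:dkey-47k20.1 (−0.67) and taar18f (−1.10) in immature, or111-6 in gnao1a-high (3.89, or 4.09 with the mitochondrial limit alone), taar19d in stm-high (−1.72) and CU104696.3 in T or NK-like cells (0.14). taar18f reversed with doublet calls kept (−0.11) and CU104696.3 at resolution 2 (0.12).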

Other observations

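The immediate-early list was also measured in classes too small for the comparisons above. In gucy1b2-high neurons, a rare class with 45 control and 44 alarm substance cells, 17 of 20 members were higher, with a median log2 ratio of 0.49 (0.28 to 0.68). In progenitor-like cells 25 of 29 members were lower (median −0.52), in tuft-like cells, which carry the pou2f3 factor of chemosensory epithelial cells, 23 of 30 were lower (−0.57), in neutrophil-like cells 12 of 14 (−0.66) in ccl35.1-high macrophage-like cells 15 of 18 (−0.82) and in atoh1a-high cells 8 of 8 (−1.27). The medians were −0.19 (−0.40 to −0.014) in ionocyte-like cells, −0.19 (−0.54 to 0.06) in superficial epithelial-like cells and 0.14 (−0.06 to 0.27) in the mixed cluster, so that the intervals of the last 2 include 0. The immature neuron-like class held 2 clusters, with medians of 0.81 and 0.47, and the basal-like class 2 clusters, with medians of −0.70 and −0.73. The 3 mature ciliated clusters had medians of 0.16 (0.031 to 0.26), 0.025 (−0.13 to 0.15) and 0.13 (0.011 to 0.21), each below the 0.19 of their class. These classes hold few cells, were looked at only after the comparisons of the larger classes were seen, and their differences were not tested.

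The gene cyp1a was higher outside the macrophage-like class as well, with log2 ratios of 2.83 (2.47 to 3.22) in multiciliated-like cells, 2.72 (2.16 to 3.39) in basal-like cells and 2.82 (1.42 to 5.35) in T or NK-like cells, and 2328 against 336 UMIs over all kept cells. The aryl hydrocarbon receptor gene ahr2 was at −0.40 in mature ciliated neuron-like cells and −0.43 in microvillous neuron-like cells. The sulfotransferase gene sult2st1 was lower in multiciliated-like cells (−2.40), basal-like cells (−1.67) and grn2-high macrophage-like cells (−1.25). The circadian activator genes npas2 (−1.57 in multiciliated-like cells) and arntl2 (−1.09 in gnao1a-high neurons) were lower where the median of their list was higher.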
